A study of Mus musculus with 10 samples.

How the data were processed

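Libraries were made from bead-captured mRNA of OP9 mouse stromal cells at day 10 of treatment with 1 µM rosiglitazone. The 10 libraries comprised 3 of a Drosha knockout and 3 of an empty vector control in batch 2, and 2 of a Dicer1 knockout and 2 of an empty vector control in batch 1. The labels name more than one RNA extraction kit and several sequencers (from MGI and Illumina) without saying which library each was used for.

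The authors deposited TPM (transcript abundance scaled to a fixed library total) per gene, 1 table per knockout, obtained with kallisto 0.48.0 per the submitters' processing notes. kallisto divides each transcript's estimated reads by its effective length before that scaling. Read trimming, the transcript index, the annotation and the genome build are not given in the sources used here. Each table held 55357 genes, and each library's TPM summed to 1e+06, so no sequencing depth could be read from it and no counting interval is given. The Dicer1 table also carried 3 columns of group means and their ratio, which were not used.

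Gene names came from the tables. In the Drosha table, 22369 genes had no symbol, and 20024 of them were named by matching their Ensembl ID to a reference table of mouse genes in which 52081 of its IDs were found. In the Dicer1 table, 22339 genes without a symbol were left out. They held between 4.25% and 6.22% of the TPM of the 4 libraries of that table. Values sharing a name were summed, which gave 55189 and 32931 named genes, with 32526 names in both tables.

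Each knockout was compared with the empty vector libraries of its own batch, because knockout and batch coincide. Genes entered when TPM was at least 1 in at least 3 of the 6 libraries (Drosha) or 2 of the 4 (Dicer1). Values were taken as log2(TPM + 1) and tested with limma 3.58.1 in R 4.3.3, two-sided, with moderated variances that follow the mean level. All adjusted p-values are Benjamini-Hochberg values, and a gene was called at an adjusted p under 0.05. The difference between the knockouts was tested in 1 limma fit of all 10 libraries on genes tested in both tables. It is the change in Drosha knockout minus the change in Dicer1 knockout. That fit gives each gene 1 spread for all groups, though the batch 1 empty vector libraries differed more than the others. Its p-values may therefore be too small for genes that varied more in batch 1. No p-value was computed between TPM levels of the batches. The closing section compares medians of cell cycle and stress genes between them without one.

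The following choices were made before the data were examined: the tests, the alternatives listed here unless said otherwise, 28 gene lists, 30 microRNA families and the rule for naming genes. The lists covered adipocyte functions, lipid and energy metabolism, other mesenchymal fates, microRNA machinery and host genes, published targets of 3 microRNA families, cell cycle, interferon, p53, stress and cytokine genes, markers of macrophages and endothelial cells, and mitochondrially encoded RNA. A list with at least 4 tested members was tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists. The rule named Drosha, Dicer1, Dgcr8, Trpm3 and Smc4, then the 8 largest rises and 8 largest falls among called genes whose groups did not overlap, with a mean TPM of at least 5 in the higher group and a symbol that is not a gene-model name. From each list it named up to 4 called members with the largest changes, or, where none was called, the 2 with the highest TPM. Some genes chosen by this rule are not reported here. For the difference between knockouts it named the 5 largest in each direction, which was applied as a mean TPM of at least 5 in the higher group of both tables and per-library changes that did not overlap between the batches.

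Seed matches were counted in the longest annotated 3′ UTR per gene, taken from a GENCODE annotation of GRCm38 that is not necessarily the one the authors used. For each family, the log2 fold change was regressed on the presence of at least 1 match to seed positions 2 to 8 with log UTR length and UTR GC content as covariates. The coefficient was placed among those of 1000 random 7-mers of the same GC count. The two-sided p is the share of random coefficients at least as far from their median, and its smallest possible value is 0.000999. The families comprised 25 test families and 5 control families restricted to other tissues. A 3′ UTR was found for 88.2% of the genes tested for Drosha and 91.8% of those tested for Dicer1.

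The alternatives were a pseudocount of 0.1 or 0.5, no filter on low TPM, a minimum TPM of 5, median-ratio scaling, quantile normalization, limma without the mean trend, a fold threshold, the replicate number as a block, leaving out each library in turn, camera with an estimated correlation, and fry, which tests whether the genes of a list move one way on balance. An estimated correlation is taken from the few libraries of a comparison, and its test has only their residual degrees of freedom. It therefore has little power here, and a call lost with it does not show that a list did not change. For seed matches, the alternatives were 8-mer sites, UTR lengths of 200 to 5000 nt and a mean TPM of at least 5. Chosen after the data were seen were fits limited to names in both tables, a fit without the Mir6236 gene, 5 further gene lists, the pooled seed test and the microRNA gene classes described in the closing section.

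The gene test was tested on simulated data drawn from the real means and spreads with normally distributed noise. Changes were put only into genes well above the minimum TPM, so recovery for genes near it was not measured. For Drosha (12739 genes), 0 genes were called when none was changed, limma recovered 96% of changes of 0.5 on the log2 scale and 100% of changes of 1, and 3.45% of its calls were false. For Dicer1 (12239 genes), 1 gene was called when none was changed, 14% of changes of 0.5 and 80% of changes of 1 were recovered, and 8.74% of calls were false. A list of 20 genes shifted by 0.5 was called in both designs. The noise was drawn independently for each gene, so this does not test list calls where genes are correlated. A simulated shift of 0.2 in genes with let-7 sites was called for Drosha (coefficient 0.208, adjusted p = 0.03) and missed for Dicer1 (0.175, adjusted p = 0.18), so 0 families called for Dicer1 does not exclude effects of that size. The pooled seed test (permutation against random 7-mers) returned p = 0.998 and 0.667 on simulated values with no effect, and 0.000999 and 0.017 with an effect of 0.02 per family, for Drosha and Dicer1. Fits and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 besides R.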

Results

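OP9 is a mouse bone marrow stromal line that can be driven to form adipocytes. RNA was sequenced from it after 10 days with 1 µM rosiglitazone, an agonist of the adipocyte regulator PPARγ. Drosha cuts primary microRNA transcripts in the nucleus, and Dicer1 cuts the released hairpins in the cytoplasm. The 10 libraries fell into 4 groups: Drosha knockout and empty vector with 3 libraries each in batch 2, and Dicer1 knockout and empty vector with 2 libraries each in batch 1. The values are TPM, which keep no record of sequencing depth, so depth is unknown. Between 12580 and 13679 genes per library reached a TPM of at least 1. Libraries of one group correlated at 0.989 to 0.990 in batch 2, at 0.982 in the Dicer1 knockout and at 0.972 in the batch 1 empty vector. The median absolute log2 difference between the batch 1 empty vector libraries was 0.218, against 0.118 for the Dicer1 knockout libraries and 0.0787 to 0.101 within the batch 2 groups. The labels do not say whether replicates were separate cultures, so all p-values measure the spread between these libraries, which may be technical.

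The first comparison asks how RNA levels differ when Drosha is lost; the series title connects Drosha to adipogenesis through miR-204 and miR-15b. TPM values are mean ± SD (n = 3 libraries per group) and changes are log2 fold changes ± SE. The targeted gene was lower in every knockout library: Drosha (ENSMUSG00000022191) stood at 38.9, 39.6 and 38.6 TPM in the empty vector libraries and at 14.8, 13.7 and 15.6 TPM in the knockout libraries (-1.35 ± 0.05, limma adjusted p = 9.72e-06). Dgcr8 (ENSMUSG00000022718), which encodes the RNA-binding partner of Drosha, rose from 18.9 ± 2.55 to 58.1 ± 5.99 TPM (1.58 ± 0.11, adjusted p = 6.00e-05). Dicer1 (ENSMUSG00000041415) rose from 9.07 ± 0.531 to 18.3 ± 1.60 TPM (0.94 ± 0.08, adjusted p = 1.32e-04). Smc4, the host gene of miR-15b, rose from 33.6 ± 1.45 to 50.5 ± 3.55 TPM (0.57 ± 0.06, adjusted p = 3.53e-04). Trpm3, the host gene of miR-204, stood at 5.18 ± 0.127 and 4.34 ± 0.254 TPM and did not pass the test (-0.21 ± 0.08, adjusted p = 0.0716). Trpm3 passed with median-ratio scaling (-0.33, adjusted p = 0.015), with quantile normalization (-0.37) and without the mean trend, and its adjusted p over all alternatives lay between 0.0116 and 0.184.

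**Figure D1:**
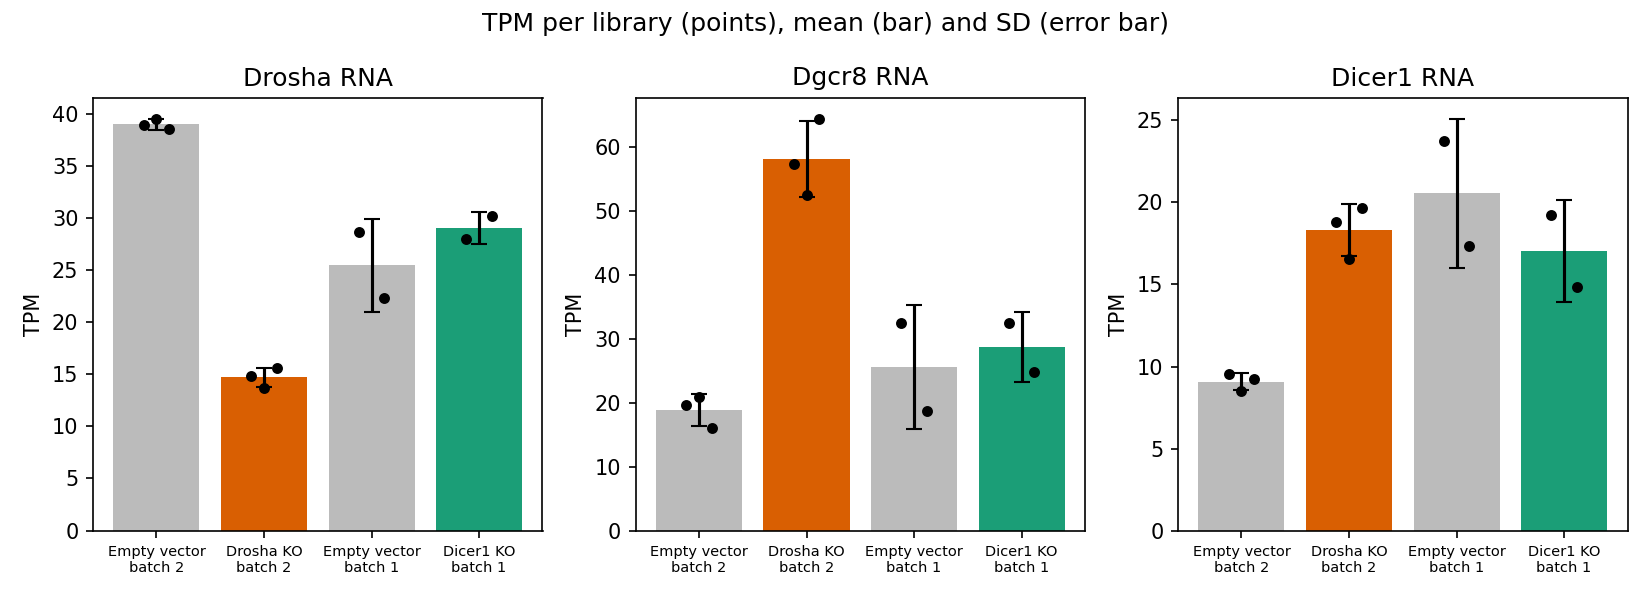
TPM (y axis) of Drosha, Dgcr8 and Dicer1 RNA in each library (points), with the mean of each group (bar) and SD (error bar). Drosha fell to 14.7 TPM in its knockout while Dgcr8 rose to 58.1 TPM, and Dicer1 RNA in the Dicer1 knockout (17.1 TPM) overlapped its empty vector (20.5 TPM); levels were tested only within a batch.

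The largest rises in Drosha knockout were mostly microRNA genes. The libraries were made from captured mRNA, so these values do not measure the mature microRNAs. Mir322 rose from 15.9 ± 2.20 to 1248 ± 231 TPM (6.20 ± 0.14), Mir503 from 24.5 ± 10.9 to 1335 ± 241 TPM (5.80 ± 0.32), Mir351 from 29.6 ± 16.8 to 796 ± 153 TPM (4.82 ± 0.34) and Mir542 from 1.82 ± 1.64 to 43.1 ± 11.8 TPM (4.17 ± 0.50). These genes neighbour each other on chromosome X. Mir29a was listed at 0 in all empty vector libraries and at 146, 162 and 186 TPM in the knockout libraries. Mir29b-1, its neighbour on chromosome 6, was listed at 0 against 35.2, 20.7 and 45.1 TPM. Mir298 was listed at 0 against 17.0, 7.53 and 31.5 TPM. The noncoding RNA Lncppara rose from 2.34 ± 0.851 to 54.6 ± 16.1 TPM (4.06 ± 0.24). Of these genes, the one with the highest adjusted p was Mir542 (limma adjusted p = 6.24e-04).

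The largest falls in Drosha knockout included products of mature fat cells. Retn, which encodes the adipokine resistin, fell from 20.9 ± 2.26 to 4.43 ± 1.18 TPM (-2.03 ± 0.16). Cfd, which encodes the adipokine adipsin, fell from 44.6 ± 0.731 to 17.5 ± 0.774 TPM (-1.30 ± 0.05). Apoc1, an apolipoprotein gene, fell from 14.4 ± 2.19 to 2.70 ± 0.509 TPM (-2.05 ± 0.14), and Mmp13, a collagenase gene, from 36.6 ± 1.46 to 9.33 ± 0.144 TPM (-1.86 ± 0.05). Ltc4s, which encodes leukotriene C4 synthase, fell from 8.01 ± 1.95 to 2.45 ± 0.494 TPM (-1.37 ± 0.17). Prxl2b (-1.32 ± 0.09) and Wfdc21 (-1.22 ± 0.16) also fell. Of these, the highest limma adjusted p was that of Wfdc21 (9.10e-04).

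Adipocyte genes fell as a group in Drosha knockout. Of 19 tested adipocyte identity genes, 16 fell, 1 rose and 2 did not pass (16 and 1 adjusted over the list alone, 17 and 1 over all genes after median-ratio scaling, median -0.67, camera adjusted p = 3.29e-14). Its called members included Adipoq, which encodes adiponectin (234.6 ± 4.65 to 110.4 ± 6.69 TPM, -1.08 ± 0.05), Rbp4 (-1.21 ± 0.07) and Adig (-1.16 ± 0.15). The list had an adjusted p = 0.158 with an estimated correlation, the highest of a range from 3.60e-15 over its alternatives. Fabp4, the fatty acid carrier of adipocytes, was the member that rose (0.36 ± 0.03). Pparg, the main adipogenic transcription factor, was looked up after the values were seen; it stood at 133.4 ± 0.195 and 137.8 ± 5.62 TPM (0.05 ± 0.04, limma adjusted p = 0.354). Of 11 lipid droplet and lipolysis genes, 6 fell and 2 rose (7 and 2 adjusted over the list alone, 8 and 1 over all genes after median-ratio scaling, median -0.37, camera adjusted p = 1.91e-04). They included Cidec (-1.05 ± 0.06) and Plin1 (-0.99 ± 0.07), which coat lipid droplets, and the lipase gene Lipe (-0.61 ± 0.08). This list had an adjusted p = 0.158 with an estimated correlation (range 4.90e-05 to 0.158). Of 18 genes of fatty acid and triglyceride synthesis, 6 fell and 4 rose (6 and 4 adjusted over the list alone, 11 and 3 over all genes after median-ratio scaling, median -0.12 and -0.26 after scaling, camera adjusted p = 0.00744). Scd1, a fatty acid desaturase gene, fell (-0.77 ± 0.07) and Me1, which encodes malic enzyme, rose (0.64 ± 0.04). That list had an adjusted p = 0.378 with an estimated correlation and 0.594 with fry (range 0.00268 to 0.594).

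Cholesterol genes rose in Drosha knockout. Of 20 genes of cholesterol synthesis and uptake, 15 rose and 0 fell (15 and 0 adjusted over the list alone, 13 and 1 over all genes after median-ratio scaling, median 0.50, camera adjusted p = 1.98e-04). The list had an adjusted p = 0.351 with an estimated correlation (range 1.06e-08 to 0.351). Of 17 fatty acid oxidation genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.18, camera adjusted p = 0.112), a split that became 2 and 3 with median-ratio scaling. That list passed with fry (0.00155) and with no filter on low values (0.00243), within a range of 0.00155 to 0.714. Of 28 oxidative phosphorylation genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone, median 0.09, camera adjusted p = 0.998); with median-ratio scaling 2 rose and 9 fell, the median was -0.06 and the adjusted p 0.0377 (range over alternatives 0.0197 to 0.999). Of 14 insulin signalling genes, 5 rose and 4 fell (5 and 4 adjusted over the list alone, 3 and 5 over all genes after median-ratio scaling, median 0.04, with camera pointing down; adjusted p = 0.235), and the median was -0.10 with median-ratio scaling. Insr, the insulin receptor gene, rose (0.57 ± 0.07) and Grb14, which encodes an inhibitor of that receptor, fell (-0.56 ± 0.07). For the 13 mitochondrially encoded RNAs, limma called 0 (2 had an unadjusted p under 0.05, 0 passed over the list alone, 2 fell after median-ratio scaling), while camera placed the list below other genes (median -0.15 and -0.30 after scaling, adjusted p = 0.00269). The mitochondrially encoded list had an adjusted p = 0.431 with an estimated correlation and lost its call with quantile normalization and with fry (0.493), within a range of 1.01e-07 to 0.894. Without empty vector replicate 2 its median was -0.00387 (0.034).

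All 23 cell cycle genes tested rose in Drosha knockout (23 adjusted over the list alone, 23 over all genes after median-ratio scaling, median 1.00, camera adjusted p = 1.13e-10). Aurka, a mitotic kinase gene, rose from 3.01 ± 0.410 to 10.3 ± 0.351 TPM (1.49 ± 0.09), Top2a, the S and G2 phase topoisomerase gene, from 11.5 ± 0.766 to 33.8 ± 3.55 TPM (1.47 ± 0.08), and Ccna2, which encodes cyclin A, from 4.96 ± 0.322 to 14.5 ± 1.58 TPM (1.38 ± 0.09). The list had an adjusted p = 0.158 with an estimated correlation (range 1.54e-18 to 0.158). Of 16 interferon response genes, 12 rose and 0 fell (13 and 0 adjusted over the list alone, 8 and 0 over all genes after median-ratio scaling, median 0.49, camera adjusted p = 0.00974), among them Usp18 (1.70 ± 0.22), which stood at 0.825 TPM in the empty vector group, and Ifit3 (0.77 ± 0.10). That list had an adjusted p = 0.369 with an estimated correlation and 0.0519 with a minimum TPM of 5 (range 7.81e-05 to 0.369). Of 17 p53 response genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone, 11 and 2 over all genes after median-ratio scaling, median 0.44, camera adjusted p = 0.00199), including the antiproliferative gene Btg2 (0.90 ± 0.06) and Gdf15 (0.87 ± 0.10). It had an adjusted p = 0.316 with an estimated correlation (range 1.51e-06 to 0.316). Of 17 genes of the integrated stress and unfolded protein response, 11 rose and 1 fell (11 and 1 adjusted over the list alone, 6 and 1 over all genes after median-ratio scaling, median 0.24 and 0.10 after scaling, camera adjusted p = 0.101). The test passed with fry (0.00178) and with no filter on low values (0.00243), within a range of 0.00178 to 0.431. Of 11 cytokine and chemokine genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone, 5 and 1 over all genes after median-ratio scaling, median 0.46, camera adjusted p = 0.0548). The chemokine gene Ccl2 rose (1.03 ± 0.08) and Lcn2, which encodes lipocalin, fell (-0.89 ± 0.08). The cytokine list was called with median-ratio scaling (adjusted p = 0.0244), quantile normalization (0.0254), no filter on low values (0.00701) and fry (5.43e-04), without empty vector replicate 2 (0.034) and without Drosha knockout replicate 3 (0.0197), within a range of 5.43e-04 to 0.351.

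Published target genes of microRNAs rose in Drosha knockout. Of 15 let-7 targets, 12 rose and 0 fell (13 and 0 adjusted over the list alone, 12 and 0 over all genes after median-ratio scaling, median 0.73, camera adjusted p = 1.47e-04). Hmga2, a chromatin gene repressed by let-7, rose from 5.86 ± 0.681 to 36.5 ± 1.20 TPM (2.46 ± 0.08), and Igf2bp1, an RNA-binding protein gene, from 4.48 ± 0.668 to 12.7 ± 1.01 TPM (1.33 ± 0.11). The let-7 list had an adjusted p = 0.261 with an estimated correlation (range 1.02e-06 to 0.261). Of 16 miR-15/16 targets, 10 rose and 0 fell (10 and 1 adjusted over the list alone, 9 and 3 over all genes after median-ratio scaling, median 0.55, camera adjusted p = 0.0496). They included the cell cycle kinase gene Wee1 (1.40 ± 0.09) and the cyclin genes Ccnd2 (0.96 ± 0.05) and Ccnd3 (0.94 ± 0.04). Cell cycle genes rose as a list here (23 of 23), so the rise of these members cannot be credited to lost miR-15/16 repression alone. The miR-15/16 list had an adjusted p = 0.261 with an estimated correlation (range 2.66e-05 to 0.261). Its call was lost without empty vector replicate 1 (0.0835) or 3 (0.0505) and without Drosha knockout replicate 1 (0.0636) or 2 (0.0528). It was also lost with a minimum TPM of 5 (0.0519), with only genes named in both tables (0.0575) and with the replicate number as a block. Of 16 miR-204 targets, 11 rose and 0 fell (11 and 0 adjusted over the list alone, 7 and 0 over all genes after median-ratio scaling, median 0.26 and 0.12 after scaling, camera adjusted p = 0.0159), with the homeobox gene Meis2 (0.61 ± 0.03) and the receptor gene Tgfbr2 (0.41 ± 0.04) among them. The miR-204 list had an adjusted p = 0.261 with an estimated correlation (range 2.23e-05 to 0.261). Of 9 noncoding host genes of microRNAs, 8 rose and 0 fell (8 and 0 adjusted over the list alone, 8 and 0 over all genes after median-ratio scaling, median 1.46, camera adjusted p = 1.98e-04). Mir22hg rose from 20.7 ± 0.962 to 116.5 ± 3.63 TPM (2.44 ± 0.05), and Dleu2, which carries miR-15a, from 14.7 ± 0.227 to 66.5 ± 8.82 TPM (2.10 ± 0.09). The noncoding hosts had an adjusted p = 0.261 with an estimated correlation (range 2.16e-06 to 0.261), and a median of 0.61 with no filter on low values. Of 25 coding host genes, 9 rose and 4 fell (9 and 4 adjusted over the list alone, median 0.14, with camera pointing down; adjusted p = 0.488), and median-ratio scaling gave 7 higher and 8 lower. Of 17 genes of the microRNA machinery, 10 rose and 1 fell (13 and 1 adjusted over the list alone, 7 and 1 over all genes after median-ratio scaling, median 0.28 and 0.13 after scaling, camera adjusted p = 0.0592). Besides Dgcr8 and Dicer1, Tnrc6a, whose protein acts with Argonaute in silencing, rose (1.29 ± 0.08), and the gene that fell was Drosha. The machinery list was called with median-ratio scaling (adjusted p = 0.0385), quantile normalization (0.0318), no filter on low values (0.00356) and fry (0.00173), and without Drosha knockout replicate 3 (0.0437), within a range of 0.00173 to 0.378.

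Among lists of other mesenchymal fates in Drosha knockout, contractile smooth muscle genes rose. Of 13 tested, 8 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.33, camera adjusted p = 0.0174), with Ccn2 (1.42 ± 0.07) and Ccn1 (0.91 ± 0.05), matrix-associated signalling genes, in the lead. The contractile list had an adjusted p = 0.351 with an estimated correlation and 0.0973 with median-ratio scaling, where 6 rose and 2 fell, and 0.0502 with a minimum TPM of 5 (range 1.53e-04 to 0.351). Of 21 extracellular matrix genes, 9 rose and 8 fell (9 and 8 adjusted over the list alone, 6 and 9 over all genes after median-ratio scaling, median 0.20 and 0.05 after scaling, with camera pointing down; adjusted p = 0.134), and Thbs1 rose (0.80 ± 0.08). Of 9 osteoblast genes, 2 fell and 0 rose (2 and 0 adjusted over the list alone, 4 and 0 over all genes after median-ratio scaling), Alpl (-0.64 ± 0.14) and Dmp1 (-0.29 ± 0.06). The osteoblast median was 0.01 (-0.14 after median-ratio scaling) and its mean -0.11, and camera placed it below other genes (adjusted p = 0.0474), with an adjusted p = 0.261 with an estimated correlation. That call was lost without empty vector replicate 3 (0.0653), without Drosha knockout replicate 2 (0.0629), with quantile normalization (0.186), with a minimum TPM of 5 (0.0502) and with fry (0.255), within a range of 0.027 to 0.261. Of 7 chondrocyte genes, 1 rose and 2 fell (2 and 2 adjusted over the list alone, 1 and 2 over all genes after median-ratio scaling, median 0.13 and 0.01 after scaling, mean -0.01, camera adjusted p = 0.115), and the median was -0.02 with quantile normalization. The chondrocyte list passed with fry (0.0455, range 0.0455 to 0.351). Of 10 mesenchymal progenitor genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone, 1 and 3 over all genes after median-ratio scaling, median 0.05, with camera pointing down; adjusted p = 0.498), and the median was -0.10 with median-ratio scaling. Of 11 adipogenesis inhibitors, 2 rose and 3 fell (3 and 3 adjusted over the list alone, 1 and 5 over all genes after median-ratio scaling, median -0.04 and -0.15 after scaling, mean 0.01, camera adjusted p = 0.0592). Their test passed without Drosha knockout replicate 3 (0.0437), within a range of 0.0437 to 0.402. Of 3 macrophage markers tested, Cd14 rose (7.26 ± 0.960 to 9.90 ± 0.839 TPM, 0.40 ± 0.11). The limma call was lost without Drosha knockout replicate 2 (adjusted p = 0.0567) or 3 (0.0596), within a range of 0.0132 to 0.107. With median-ratio scaling and with quantile normalization 0 of the 3 were called. No endothelial marker and no thermogenic gene reached the minimum TPM.

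In all, 5447 of 12739 tested genes were called in Drosha knockout (limma, Benjamini-Hochberg), 4502 higher and 945 lower, of which 247 and 35 changed by at least 1 on the log2 scale. The groups did not overlap for 54.8% of genes, where chance gives 10%. Median-ratio scaling shifted the fold changes by 0.147 and called 2297 higher and 2091 lower, so the share of calls that were higher was 82.7% as deposited and 52.3% after scaling. Camera called 14 of 25 lists. With an estimated correlation camera called 0 lists, with 3 at an unadjusted p under 0.05, and fry called 18. That 0 comes from a test with little power for so few libraries.

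The second comparison asks the same question for Dicer1. TPM values are mean ± SD (n = 2 libraries per group). The targeted RNA overlapped between the groups: Dicer1 stood at 23.8 and 17.3 TPM in the empty vector libraries and at 19.3 and 14.9 TPM in the knockout libraries (-0.25 ± 0.21, limma adjusted p = 0.407). The RNA level of Dicer1 therefore does not check the knockout label; a small edit can leave RNA abundance as it was. Drosha stood at 25.5 ± 4.45 and 29.1 ± 1.56 TPM (0.19 ± 0.15, adjusted p = 0.383), and Dgcr8 at 25.6 ± 9.66 and 28.7 ± 5.43 TPM (0.20 ± 0.28, adjusted p = 0.624). Smc4 fell from 44.4 ± 11.4 to 24.9 ± 3.46 TPM (-0.79 ± 0.21, adjusted p = 0.038), a call lost without Dicer1 knockout replicate 1 (0.184) or 2 (0.0881), within a range of 0.00656 to 0.184, with Smc4 at -0.66 and -0.93 there. In this comparison a fit without 1 library holds a group of 1, so the other group alone gives the spread, and such a p says little about the size of a change.

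The largest falls in Dicer1 knockout included heat shock and fat cell genes. Adipoq, which encodes adiponectin, fell from 49.0 ± 17.8 to 0.156 ± 0.0114 TPM (-5.39 ± 0.29), and Plin1, the main lipid droplet coat protein gene of adipocytes, from 46.4 ± 19.7 to 0.407 ± 0.00103 TPM (-5.01 ± 0.32). The chaperone genes Hspa1a (333 ± 197 to 0.660 ± 0.260 TPM, -7.52 ± 0.42), Hspb1 (103 ± 72.3 to 1.09 ± 0.516 TPM, -5.46 ± 0.51) and Hspa1b (-5.02 ± 0.43) fell. Hspa1b stood at 1793 and 4746 TPM in the empty vector libraries and at 90.8 and 86.8 TPM in the knockout libraries. Hspa1a and Hspa1b are near-identical, so the share of reads given to each is uncertain. Clu, which encodes the chaperone clusterin (-4.72 ± 0.25), the neuronal activity gene Arc (-4.41 ± 0.41) and Agt, which encodes angiotensinogen (-4.31 ± 0.24), fell as well. Among the largest rises were Clec4e, a C-type lectin gene (0.955 ± 0.0992 to 31.7 ± 0.486 TPM, 4.07 ± 0.17), Csf2, which encodes a myeloid growth factor (2.59 ± 0.230 to 34.8 ± 1.09 TPM, 3.32 ± 0.16), and Cxcl2, a neutrophil chemokine gene (8.65 ± 0.653 to 85.7 ± 8.49 TPM, 3.17 ± 0.13). Serpinb9b (3.62 ± 0.13) and the enolase gene Eno1b (3.28 ± 0.18) rose too. Mir6904 was listed at 0 in both empty vector libraries and at 22.0045 and 9.01 TPM in the knockout libraries. Mir1932 (3.47 ± 0.65) lost its call without Dicer1 knockout replicate 1 (adjusted p = 0.0622) or 2 (0.0569), within a range of 8.55e-04 to 0.0747. Snord73a (3.52 ± 0.77) lost it without replicate 2 (0.085), within a range of 0.00332 to 0.0974. Of the 16 largest changes, the highest limma adjusted p was that of Snord73a (0.025).

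Adipocyte genes fell in Dicer1 knockout. Of 16 adipocyte identity genes, 12 fell and 0 rose (12 and 0 adjusted over the list alone, 12 and 0 over all genes after median-ratio scaling, median -1.74, camera adjusted p = 1.11e-09). Gpd1, an enzyme of glycerol phosphate supply (-3.85 ± 0.34), the fatty acid transporter gene Cd36 (-3.52 ± 0.22) and Cfd (-2.87 ± 0.25) fell. Adig and Lgals12 were listed at 0 in both knockout libraries, against means of 4.69 and 1.39 TPM. Pparg stood at 121.9 ± 2.07 and 113.0 ± 2.58 TPM (-0.11 ± 0.08, limma adjusted p = 0.352), and Cebpa, another adipogenic transcription factor, fell (-1.19 ± 0.12, adjusted p = 0.00564); both were looked up after the values were seen. The adipocyte list had an adjusted p = 0.352 with an estimated correlation (range 4.39e-12 to 0.352). Its median was nearer to 0 without either empty vector library, at -0.92 without replicate 1. Of 11 lipid droplet and lipolysis genes, 5 fell and 1 rose (5 and 2 adjusted over the list alone, 6 and 1 over all genes after median-ratio scaling, median -0.38, camera adjusted p = 0.00747). G0s2 (-3.31 ± 0.26) and Cidec (-2.62 ± 0.26) fell. The lipid droplet list had an adjusted p = 0.352 with an estimated correlation and lost its call without empty vector replicate 2 (0.0973), within a range of 0.00316 to 0.352, and its median was -0.13 without empty vector replicate 1. Of 18 genes of fatty acid and triglyceride synthesis, 4 fell and 1 rose (2 and 1 adjusted over the list alone, 8 and 1 over all genes after median-ratio scaling, median -0.26 and -0.43 after scaling, camera adjusted p = 0.00747), with Scd1 in the lead (-2.70 ± 0.15). That list had an adjusted p = 0.352 with an estimated correlation (range 0.00573 to 0.352). Of 14 thermogenic genes 3 were tested, and limma called 0 of these and 0 over the list alone (1 at an unadjusted p under 0.05). Cox7a1 stood at 12.7 ± 3.79 and 6.50 ± 1.27 TPM (limma adjusted p = 0.0576). It passed without empty vector replicate 1, and its log2 change ran from -1.13 to -0.56 over the alternatives.

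Few cholesterol genes were called in Dicer1 knockout, though camera placed their list below other genes. Of 20 genes of cholesterol synthesis and uptake, 3 fell and 0 rose (2 and 0 adjusted over the list alone, 6 and 0 over all genes after median-ratio scaling, median -0.26 and -0.42 after scaling, camera adjusted p = 0.00153), among them Idi1 and Fdps. Both lost their calls without Dicer1 knockout replicate 1 or 2, where their adjusted p lay between 0.0525 (Idi1) and 0.255 (Fdps), though Idi1 stayed at -1.67 and -1.37 and Fdps at -0.51 and -0.61. The list had an adjusted p = 0.352 with an estimated correlation and lost its call with fry (0.0866), which tests against no change, within a range of 0.00134 to 0.352. Of 17 fatty acid oxidation genes, 3 fell and 1 rose (3 and 1 adjusted over the list alone, 6 and 0 over all genes after median-ratio scaling, median -0.01 and -0.17 after scaling, camera adjusted p = 0.119). The test passed with quantile normalization (0.0332, median -0.19), within a range of 0.0332 to 0.596. The median was -0.18 without empty vector replicate 2 and ran from -0.19 to 0.16 over the alternatives. Of 28 oxidative phosphorylation genes, 3 fell and 0 rose (3 and 0 adjusted over the list alone, 7 and 0 over all genes after median-ratio scaling, median -0.15 and -0.32 after scaling, camera adjusted p = 0.00747), Cox6a1, Ndufb9 and Cox4i1. All of these lost their calls without either Dicer1 knockout replicate, with adjusted p up to 0.228 (Cox4i1), though Cox4i1 stayed at -0.35 in both. The oxidative phosphorylation list had an adjusted p = 0.352 with an estimated correlation and 0.207 with fry (range 1.13e-04 to 0.352), and its median was -0.04 without empty vector replicate 1. Of 13 insulin signalling genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, 1 and 3 over all genes after median-ratio scaling, median -0.22 and -0.38 after scaling, camera adjusted p = 0.147), with Grb14 the one whose call held without any one library (-1.15 ± 0.11). The insulin signalling median ran from -0.46 to 0.01 over the alternatives. For the 13 mitochondrially encoded RNAs limma called 0 (2 at an unadjusted p under 0.05, 0 over the list alone, 3 fell after median-ratio scaling), while camera placed the list below other genes (median -0.22 and -0.39 after scaling, adjusted p = 0.0157). It had an adjusted p = 0.567 with an estimated correlation and lost its call without Dicer1 knockout replicate 1 (0.0685), with no filter on low values (0.0676), with quantile normalization (0.226) and with fry (0.508), within a range of 1.42e-04 to 0.567. Without empty vector replicate 1 the call was lost too (0.213) and the median was -0.00973, so the shift depended on that library.

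Cell cycle genes fell in Dicer1 knockout: of 23 tested, 20 fell and 0 rose (21 and 0 adjusted over the list alone, 22 and 0 over all genes after median-ratio scaling, median -1.65, camera adjusted p = 3.27e-13). Ccnb1, which encodes cyclin B, fell from 44.5 ± 21.4 to 4.08 ± 0.616 TPM (-3.08 ± 0.34), Ube2c, an anaphase ubiquitin enzyme gene, from 121 ± 60.8 to 17.99 ± 3.95 TPM (-2.60 ± 0.36), and the mitotic kinase gene Plk1 from 26.0 ± 12.6 to 3.85 ± 0.185 TPM (-2.39 ± 0.34). The list had an adjusted p = 0.401 with an estimated correlation and 0.097 with fry (range 2.06e-17 to 0.401). Of 23 interferon response genes, 8 fell and 1 rose (10 and 1 adjusted over the list alone, 10 and 1 over all genes after median-ratio scaling, median -0.74, camera adjusted p = 1.40e-06), led by the chemokine gene Cxcl10 (-2.26 ± 0.30) and the transcription factor gene Irf7 (-1.79 ± 0.15). The interferon list had an adjusted p = 0.463 with an estimated correlation and 0.134 with fry (range 3.45e-09 to 0.463), and its median was -0.35 without empty vector replicate 1. Cytokine and chemokine genes rose: of 14 tested, 11 rose and 1 fell (11 and 2 adjusted over the list alone, 11 and 2 over all genes after median-ratio scaling, median 1.03, camera adjusted p = 9.86e-04). Besides Cxcl2, Ptgs2, the inducible prostaglandin synthase gene (82.3 ± 11.9 to 539 ± 26.4 TPM, 2.70 ± 0.12), the chemokine gene Cxcl1 (2.19 ± 0.09) and Lif (1.56 ± 0.13) rose. The cytokine list had an adjusted p = 0.352 with an estimated correlation (range 1.39e-05 to 0.352). Of 17 genes of the integrated stress and unfolded protein response, 11 rose and 1 fell (12 and 1 adjusted over the list alone, 9 and 1 over all genes after median-ratio scaling, median 0.72, camera adjusted p = 0.00259), including Trib3 (1.61 ± 0.22) and the transcription factor gene Atf4 (1.07 ± 0.11). It had an adjusted p = 0.352 with an estimated correlation (range 3.27e-04 to 0.352). Atf3 was the member that fell, a call lost without Dicer1 knockout replicate 1 (0.0566) or 2 (0.0578), within a range of 7.54e-04 to 0.0759. Of 17 p53 response genes, 8 rose and 0 fell (9 and 0 adjusted over the list alone, 6 and 0 over all genes after median-ratio scaling, median 0.49 and 0.32 after scaling, camera adjusted p = 0.0157), led by Trp53inp1 (1.48 ± 0.11). The p53 list had an adjusted p = 0.352 with an estimated correlation (range 0.0037 to 0.352).

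Target genes of let-7 rose in Dicer1 knockout. Of 15 tested, 10 rose and 0 fell (12 and 0 adjusted over the list alone, 9 and 0 over all genes after median-ratio scaling, median 0.70, camera adjusted p = 9.86e-04). Arid3a rose from 3.02 ± 0.258 to 26.3 ± 1.06 TPM (2.76 ± 0.16) and Hmga2 from 221 ± 13.2 to 569 ± 21.7 TPM (1.36 ± 0.09). The let-7 list had an adjusted p = 0.352 with an estimated correlation (range 1.29e-04 to 0.352). Of 16 miR-15/16 targets, 7 rose and 1 fell (10 and 1 adjusted over the list alone, 6 and 1 over all genes after median-ratio scaling, median 0.65, camera adjusted p = 0.0482), among them Vegfa (0.94 ± 0.08). The miR-15/16 list had an adjusted p = 0.352 with an estimated correlation and lost its call without empty vector replicate 2 (0.0762) or Dicer1 knockout replicate 2 (0.0744), with a pseudocount of 0.1 (0.0501) and with a minimum TPM of 5 (0.105), within a range of 0.018 to 0.352. Ccne1 was the member that fell (-0.97 ± 0.16), a call lost without either Dicer1 knockout replicate (0.106 and 0.0588), within a range of 0.00777 to 0.106. Of 16 miR-204 targets, 6 rose and 0 fell (6 and 0 adjusted over the list alone, 3 and 1 over all genes after median-ratio scaling, median 0.34 and 0.18 after scaling, camera adjusted p = 0.261; 0.0209 with fry, range 0.0209 to 0.465), with Sox4 (1.30 ± 0.18) losing its call without Dicer1 knockout replicate 1 (0.0504, range 0.00118 to 0.0504). Of 17 machinery genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone, 3 and 0 over all genes after median-ratio scaling, median 0.45 and 0.29 after scaling, camera adjusted p = 0.0405). Ago2, the slicing Argonaute gene, rose (0.95 ± 0.15), a call lost without Dicer1 knockout replicate 1 (0.0814) or 2 (0.0599), within a range of 0.00219 to 0.0814, though Ago2 stayed at 0.92 and 0.99. The machinery list had an adjusted p = 0.463 with an estimated correlation and lost its call without empty vector replicate 2 (0.108) or Dicer1 knockout replicate 1 (0.0684), with a minimum TPM of 5 (0.098) and with fry (0.071), within a range of 0.0108 to 0.463. Of 6 noncoding host genes limma called 0 (2 at an unadjusted p under 0.05, 0 over the list alone, 1 fell after median-ratio scaling, median -0.16 and -0.32 after scaling, camera adjusted p = 0.273). Of 22 coding host genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone, 2 and 4 over all genes after median-ratio scaling, median 0.16, with camera pointing down; adjusted p = 0.912), and the median was -0.01 with median-ratio scaling.

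In Dicer1 knockout camera placed extracellular matrix, mesenchymal progenitor and osteoblast genes below other genes. Of 22 extracellular matrix genes, 9 fell and 6 rose (9 and 6 adjusted over the list alone, 10 and 4 over all genes after median-ratio scaling, median -0.25 and -0.42 after scaling, camera adjusted p = 0.0158). Col6a2 fell from 768 ± 136 to 143 ± 2.06 TPM (-2.40 ± 0.13) and Col6a1 from 831 ± 114 to 192 ± 4.57 TPM (-2.10 ± 0.11). The matrix list had an adjusted p = 0.567 with an estimated correlation and lost its call with quantile normalization (0.0531), with no filter on low values (0.0909, median -0.18) and with fry (0.222), within a range of 0.00369 to 0.567. The matrix median was -0.10 without empty vector replicate 1 and -0.38 without replicate 2. Of 14 mesenchymal progenitor genes, 7 fell and 2 rose (7 and 2 adjusted over the list alone, 8 and 1 over all genes after median-ratio scaling, median -0.35, camera adjusted p = 0.00747), with the growth factor receptor gene Pdgfrb (-2.13 ± 0.23) and Ly6a (-1.57 ± 0.21) among those that fell. The progenitor list had an adjusted p = 0.352 with an estimated correlation and 0.0914 with fry (range 0.00539 to 0.352), and a median of -0.19 with no filter on low values. Of 7 osteoblast genes, 3 fell and 0 rose (3 and 0 adjusted over the list alone, 3 and 0 over all genes after median-ratio scaling, median -0.51, camera adjusted p = 0.00888), led by Alpl, which encodes alkaline phosphatase (61.8 ± 11.4 to 9.10 ± 0.0851 TPM, -2.62 ± 0.16). The osteoblast list had an adjusted p = 0.352 with an estimated correlation and lost its call with no filter on low values (median -0.04, 0.0768), within a range of 0.00609 to 0.352. Of 13 contractile smooth muscle genes, 4 rose and 3 fell (4 and 7 adjusted over the list alone, 4 and 5 over all genes after median-ratio scaling, median -0.63, camera adjusted p = 0.108); Ccn2 rose (1.71 ± 0.12) and the actin gene Actg2 fell (-2.24 ± 0.27). Of 5 chondrocyte genes, 1 rose and 2 fell (1 and 3 adjusted over the list alone, 1 and 2 over all genes after median-ratio scaling, median -0.63, camera adjusted p = 0.193), with the cartilage collagen gene Col2a1 among the latter (-1.78 ± 0.17). Both lists passed without empty vector replicate 1 (0.0374), within ranges of 0.0374 to 0.982 and 0.0374 to 0.465. In that fit the contractile median shrank to -0.37 and the chondrocyte median was -0.90. Of 12 adipogenesis inhibitors, 2 rose and 3 fell (2 and 5 adjusted over the list alone, 2 and 4 over all genes after median-ratio scaling, median -0.18 and -0.34 after scaling, mean 0.06, camera adjusted p = 0.207), and Mmp3 rose (2.32 ± 0.19). Of the 2 macrophage markers tested, limma called 0 (0 at an unadjusted p under 0.05, 0 over the list alone), with Cd14 at 16.5 ± 0.216 and 18.6 ± 0.713 TPM. No endothelial marker reached the minimum TPM.

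In all, 3802 of 12239 tested genes were called in Dicer1 knockout (limma, Benjamini-Hochberg), 2627 higher and 1175 lower, of which 539 and 597 changed by at least 1 on the log2 scale. The groups did not overlap for 70.1% of genes, where chance gives 33.3%. Median-ratio scaling shifted the fold changes by 0.173 and called 1513 higher and 1672 lower (69.1% higher as deposited, 47.5% after scaling). The count was 432 without Dicer1 knockout replicate 1 and 679 without replicate 2, and 50 of 99 and 43 of 99 called genes chosen by the naming rule lost their calls in these fits. With 1 knockout library in them, the empty vector pair alone gave the spread. The count was 4769 without empty vector replicate 1 and 4670 without replicate 2, where the knockout pair gave it. So these counts do not show that a knockout library carried the changes. Camera called 17 of 25 lists, 0 with an estimated correlation (1 at an unadjusted p under 0.05), and fry called 10.

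**Figure D2:**
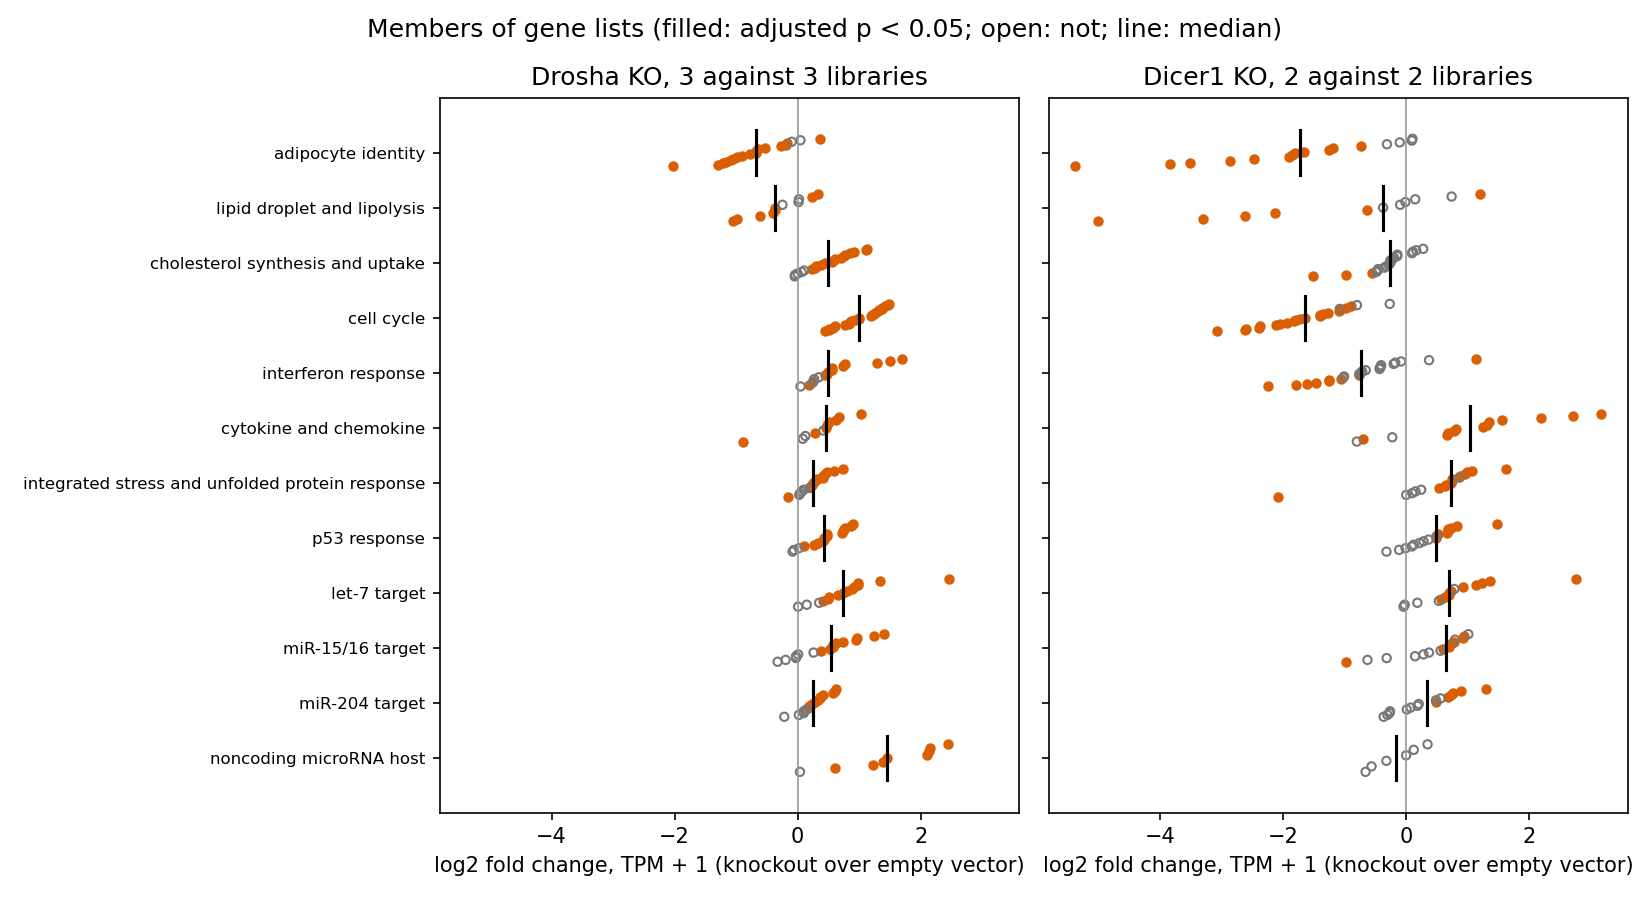
Log2 fold change (x axis) of each tested member of 12 gene lists (y axis) in Drosha knockout (left) and Dicer1 knockout (right); filled points were called, open points were not, and lines are medians. Cell cycle genes lie to the right in Drosha knockout (median 1.00) and to the left in Dicer1 knockout (median -1.65), while adipocyte genes lie to the left in both (-0.67 and -1.74).

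The third comparison asks whether the knockouts changed the same genes differently. Cell cycle genes differed most among the lists: the change was higher in Drosha knockout for 23 of 23 (median difference 2.72, camera adjusted p = 3.15e-16). It had an adjusted p = 0.319 with an estimated correlation. For Ube2c the difference was 4.02 (limma adjusted p = 3.97e-05). Adipocyte genes fell by less in Drosha knockout than in Dicer1 knockout, with 11 of 16 differing in that direction and 1 in the other (median 0.92, and 1.84 with a pseudocount of 0.1, adjusted p = 1.09e-05; adjusted p = 0.260 with an estimated correlation). Cholesterol genes had higher changes in Drosha knockout for 15 of 20 (0.79, adjusted p = 2.18e-07; adjusted p = 0.288 with an estimated correlation), and interferon response genes for 13 of 16 (1.40, adjusted p = 8.30e-06; adjusted p = 0.386 with an estimated correlation). The let-7 targets had no called difference as a list (median 0.06, camera adjusted p = 0.912), nor did the miR-15/16 targets (0.05, adjusted p = 0.962) or the miR-204 targets (-0.06, adjusted p = 0.915). Members differed both ways, with 4 higher and 4 lower in Drosha knockout of 15 let-7 targets. These counts were 4 and 5 of 16 for miR-15/16 and 4 and 4 of 16 for miR-204. By camera, changes were also higher in Drosha knockout for noncoding host genes (4 of 6 higher and 0 lower, 2.02, adjusted p = 0.00122) and mesenchymal progenitor genes (6 of 10 and 1, 0.64, adjusted p = 0.0122). So were changes of extracellular matrix genes (11 of 21 and 3, 0.32, adjusted p = 0.00777) and oxidative phosphorylation genes (7 of 25 and 1, 0.23, adjusted p = 0.0454). They were lower for the integrated stress and unfolded protein response (-0.32, adjusted p = 0.0161), a call lost without empty vector batch 1 replicate 1 (0.0649, range 0.00279 to 0.0649). The call for oxidative phosphorylation was lost without empty vector batch 1 replicate 1 (0.063, median 0.0779) or batch 2 replicate 3 (0.0546), Dicer1 knockout replicate 1 (0.063) or Drosha knockout replicate 2 (0.0627), within a range of 0.0214 to 0.063. These lists had an adjusted p between 0.312 and 0.565 with an estimated correlation. Camera did not call lipid droplet genes (0.34, adjusted p = 0.0721), fatty acid and triglyceride synthesis (0.17, 0.0721), fatty acid oxidation (0.22, 0.0567), insulin signalling (0.27, 0.288), adipogenesis inhibitors (0.09, 0.582), osteoblast genes (0.43, 0.0573) or chondrocyte genes (0.33, 0.323). Nor did it call contractile genes (0.83, 0.0721), microRNA machinery (-0.13, 0.709), coding host genes (0.03, 0.524), p53 response genes (0.02, 0.916), cytokine genes (-0.49, 0.0583) or mitochondrially encoded RNA (0.02, 0.915). Of these, 6 passed in at least 1 fit without a library, and their lowest adjusted p is given with the range over alternatives. These were fatty acid oxidation without empty vector batch 1 replicate 2 (0.0183, range 0.0183 to 0.12), contractile genes without empty vector batch 1 replicate 1 (0.0256, range 0.0256 to 0.126) and cytokine genes without Dicer1 knockout replicate 1 (0.0356, range 0.0356 to 0.162). Osteoblast genes passed without Drosha knockout replicate 1 (0.0453, range 0.0453 to 0.0999), as did fatty acid and triglyceride synthesis (0.0486, range 0.0486 to 0.12), and lipid droplet genes passed without Dicer1 knockout replicate 1 (0.0493, range 0.0493 to 0.162). Of 11146 genes tested, limma called 3960, 1944 with a higher and 2016 with a lower change in Drosha knockout. The fit pools the unlike spreads of the batches, so this count may be too high. Camera called 9 of 25 lists, and 0 with an estimated correlation (3 at an unadjusted p under 0.05). Knockout and batch coincide, so a difference between the knockouts cannot be told apart from one between the batches.

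Across genes, which are not independent replicates, the fold changes of the knockouts correlated weakly (Pearson r = 0.141, Spearman rho = 0.235, covariance 0.0287; 11146 genes). The knockouts share no control libraries. Both rose for 1444 genes, where independent calls would give 944, and both fell for 280, where they would give 77.4. Opposite calls were made for 324 genes that rose in Drosha knockout and fell in Dicer1 knockout (406 if independent) and for 84 in the reverse direction (180 if independent). Among the genes that rose in both was the let-7 target Hmga2, and its rise was larger in Drosha knockout (difference 1.10, limma adjusted p = 1.22e-04). It stood at 5.18, 6.54 and 5.86 TPM in the batch 2 empty vector libraries and at 231 and 212 TPM in those of batch 1. The rises thus began at unlike levels. Without empty vector batch 1 replicate 2 the correlation was 0.0839.

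The fourth comparison asks whether genes with seed matches for a microRNA family in the 3′ UTR changed differently from genes without them. By the permutation test against random 7-mers, genes with a miR-26 site had in Drosha knockout a coefficient of 0.055 on the log2 scale (p = 0.002, adjusted p = 0.0599), let-7 sites 0.062 (adjusted p = 0.0899) and miR-15/16 sites 0.0502 (adjusted p = 0.0899). The miR-204 site coefficient was -0.00451, at percentile 50.2 of the random 7-mers. That test called 0 of 30 families in either knockout. At an unadjusted p under 0.05 stood 10 of 25 test families in Drosha knockout, all higher, and 5 of 25 in Dicer1 knockout, all higher. Among the 5 control families 1 stood there in each knockout, miR-375 (-0.0579 and -0.0752). In Dicer1 knockout the lowest adjusted p was 0.216. miR-26 passed in Drosha knockout when any one library was left out (adjusted p = 0.03 in each), so the 0 there rests on a value close to the threshold. Among 30 families a single one could pass only at the smallest possible p, 0.000999. The 0 therefore depends on the number of random 7-mers too.

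**Figure D3:**
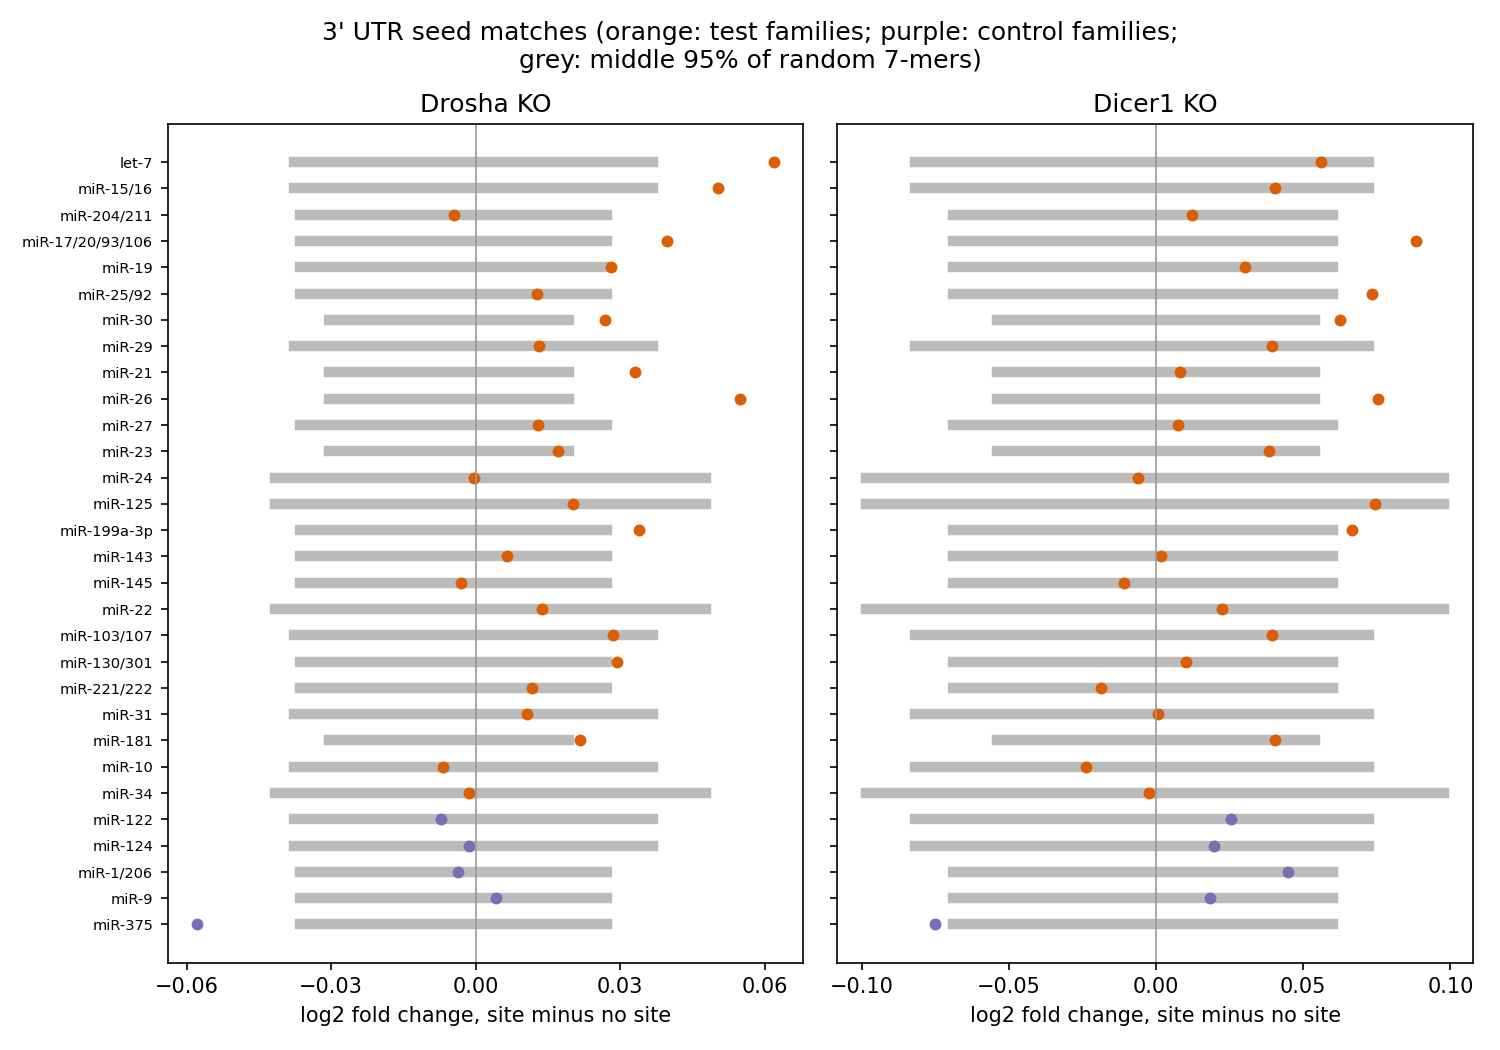
Coefficient of seed matches on the log2 fold change (x axis) for 30 microRNA families (y axis) in Drosha knockout (left) and Dicer1 knockout (right), with test families in orange, control families in purple and the middle 95% of random 7-mers in grey. 10 test families lie beyond the unadjusted threshold in Drosha knockout and 5 in Dicer1 knockout, and the miR-204 coefficient in Drosha knockout (-0.00451) lies at the centre of the random values.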

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

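The tests of microRNA genes, of batch levels, of stress genes and of pooled seed sites, and the limits they were read with, were chosen only after the results were seen, while the single-library test of cell cycle genes and the regrouping of libraries were set before. The change in Drosha knockout minus that in Dicer1 knockout was called by limma for 3960 genes, in a fit that pools the unlike spreads of the batches. It was -1.54 for Drosha, 1.19 for Dicer1, 1.38 for Dgcr8 and 1.36 for Smc4. It was 4.88 for the chaperone gene Hspa1b, 4.56 for the immediate early gene Fos and 4.45 for Clu. On the log2 scale Mir296 differed by 7.56 and Mir145a by 5.74. These values depend on the pseudocount, because Mir296 was listed at 0 in the batch 2 empty vector and the Dicer1 knockout, and Mir145a in the Dicer1 knockout. It was -2.63 for the hypoxia gene Ndrg1, -2.41 for the DNA damage gene Gadd45a, -2.34 for Ets2, -2.28 for Nrp2 and -2.19 for Gpt. Among lists, the median difference was 0.92 for adipocyte identity (1.84 with a pseudocount of 0.1), 0.79 for cholesterol synthesis and uptake, 2.72 for cell cycle and 1.40 for interferon response. It was 2.02 for noncoding microRNA hosts, 0.64 for mesenchymal progenitor genes, 0.32 for extracellular matrix and -0.32 for the integrated stress and unfolded protein response (camera adjusted p = 0.0161, and 0.0649 without empty vector batch 1 replicate 1, within a range of 0.00279 to 0.0649). For oxidative phosphorylation it was 0.23 (adjusted p = 0.0454), which lost its call without Dicer1 knockout replicate 1 (0.063), Drosha knockout replicate 2 (0.0627), empty vector batch 2 replicate 3 (0.0546) or empty vector batch 1 replicate 1 (0.063), within a range of 0.0214 to 0.063. In the last of these fits its median difference was 0.0779. The called differences of the 9 lists had an adjusted p between 0.260 and 0.565 with an estimated correlation. Of the 10 ways to split the 6 batch 2 libraries into groups of 3, the real one called 5447 genes and the highest other called 1, and 1 of 10 is too few splits for a share under 0.05.

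MicroRNA genes rose in Drosha knockout, 24 of 43 tested, with 1 falling (median 1.38). Of the 43, 11 were listed at 0 in all empty vector libraries and so entered only through the knockout, which favours a rise. Among 30 other small RNAs this held for 1. Short genes gaining TPM because of their length would raise other small RNAs alike, but their median change was 0.23. Longer unprocessed host transcripts are in line with the median of 1.46 for noncoding host genes, but the 25 coding host genes had a median of 0.14 where all tested genes had 0.13. The 23 microRNA genes tested in both tables had a median change of 1.05 in Drosha knockout, where 11 rose. In Dicer1 knockout their median was 0.70 with a standard error of 0.38, and 3 rose and 3 fell. Gene by gene, the change in Drosha knockout minus that in Dicer1 knockout had a median of -0.0995. By limma 4 of these differences were called higher in Drosha knockout and 3 lower. Mir322, Mir503, Mir351, Mir542 and Mir29a were not among those tested for Dicer1. Of 6 noncoding host genes 0 were called in Dicer1 knockout (median -0.16). Whether the rise goes with Drosha alone stays open, because the 0.70 is too uncertain to tell. The differences of the 23 shared genes leaned to neither knockout. In Dicer1 knockout 10 of 65 microRNA genes rose and 8 fell, Mir6236 among the latter.

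Cell cycle genes changed in opposite directions, up in Drosha knockout and down in Dicer1 knockout. No single library made this, since the leave-one-out medians nearest to 0 were 0.97 and -1.16. Scaling did not make it either, with medians of 0.88 and -1.82 after median-ratio scaling. Different proliferation of the empty vector cultures is in line with a median 2.25 higher in the batch 1 than in the batch 2 empty vector, while the knockout groups differed by -0.49. That value compares batches, so culture and batch cannot be told apart.

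Heat shock and immediate early genes were lower in Dicer1 knockout (median -0.45). Without empty vector batch 1 replicate 2 the median was -0.23 and without replicate 1 it was -0.74, so the size, though not the direction, rested on which control was kept. Stressed batch 1 control cultures might account for it, as these genes were 2.05 higher in the batch 1 than in the batch 2 empty vector. The knockout groups differed the same way by 1.24, so batch and stress cannot be told apart.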

How the results depend on the processing

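Results that moved under another choice were as follows, and unless said the cause was not tested. Asking for an absolute log2 fold change of at least 1 left 282 genes called in Drosha knockout and 1136 in Dicer1 knockout, which follows from the stricter rule. In Dicer1 knockout 1847 genes were called with no filter on low values, and leaving out 1 library gave 432 to 4769, where a group of 1 is left and the other group alone gives the spread. Camera with an estimated correlation, which has little power for so few libraries, called 0 lists in Drosha knockout and 0 in Dicer1 knockout. In Dicer1 knockout fry called 10. The agreement of the knockouts across genes (r) was 0.0931 with a pseudocount of 0.1, 0.193 at a mean TPM of at least 5, and 0.0839 to 0.162 with 1 library left out. Families with a seed-site effect in Drosha knockout numbered 1 with UTRs of 200 to 5000 nt, 1 at a mean TPM of at least 5 and 1 without any one library. Reversed was the oxidative phosphorylation list in Drosha knockout with median-ratio scaling (median -0.0601, adjusted p = 0.0377). The mitochondrially encoded RNA list lost its call there with quantile normalization (median -0.047, adjusted p = 0.894), where the direction from camera turned but the median stayed below 0. The coding microRNA host list in Drosha knockout pointed up with fry (median 0.14, adjusted p = 0.0306), which tests a list against no change and not against other genes. Mir100hg in Dicer1 knockout was 0.38 (limma adjusted p = 0.0222) without empty vector batch 1 replicate 1 and -0.38 (adjusted p = 0.0201) without replicate 2. With the replicate number as a replicate block, 5188 genes were called in Drosha knockout, 3045 in Dicer1 knockout and 3433 for their difference. In Drosha knockout the miR-15/16 list lost its call with the block (0.0541) and the microRNA machinery list gained one (0.0397). Of named genes 8 lost theirs in one knockout or the other, among them Fdps (0.0675), Cox4i1 (0.0621) and Ndufb9 (0.0568) in Dicer1 knockout, and 1 gained one, with unchanged log2 changes.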

Other observations

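Of further gene lists, chosen after the data were seen, ribosomal protein genes fell, 70 of 77 in Drosha knockout and 51 of 78 in Dicer1 knockout, with 0 rising in either (medians -0.30 and -0.39). Their share of all TPM fell from 17.4 ± 0.226% to 14.1 ± 0.365% in Drosha knockout (n = 3) and from 15.2 ± 0.900% to 11.4 ± 0.108% in Dicer1 knockout (n = 2). Rps6 fell from 2583 to 1943 TPM in Drosha knockout (-0.41 ± 0.04). A loss of this share raises the TPM of all other genes, and after median-ratio scaling 74 and 59 of these genes fell. The list had an adjusted p = 0.0733 with an estimated correlation in Drosha knockout and 0.444 in Dicer1 knockout.

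Genes of glycolysis and hypoxia rose in Dicer1 knockout, 17 of 24 with 0 falling (median 0.58, camera adjusted p = 1.76e-05). After median-ratio scaling 8 rose and 0 fell, with a median of 0.41. Hk2, which encodes hexokinase, rose from 33.6 ± 7.23 to 92.9 ± 5.41 TPM (1.46 ± 0.16), and Ero1a, an oxidase gene induced by hypoxia, from 466 ± 141 to 1334 ± 89.2 TPM (1.55 ± 0.21). In Drosha knockout the list was not called (adjusted p = 0.594), with 8 of 22 higher and 2 lower, and 4 higher and 8 lower after scaling. Lysosome genes rose in Dicer1 knockout, 12 of 19 with 0 falling (adjusted p = 0.00251), and 5 rose after scaling. In Drosha knockout the lysosome list was not called (adjusted p = 0.0593), with 13 of 20 higher and 1 lower, and 6 higher and 6 lower after scaling. Immediate early genes rose in Drosha knockout, 10 of 17 with 2 falling (adjusted p = 0.0369), with Fos (1.77 ± 0.12) and Nr4a1 (1.14 ± 0.09) among them, and in Dicer1 knockout 4 of 18 rose and 8 fell (adjusted p = 0.00985). Heat shock genes fell in Dicer1 knockout, 7 of 17 with 1 rising (adjusted p = 1.76e-05), such as Cryab (-3.97 ± 0.40). In Drosha knockout the heat shock list was not called (adjusted p = 0.780), with 5 of 15 higher and 1 lower, and 4 higher and 7 lower after scaling. These 4 lists had an adjusted p between 0.444 and 0.468 in Dicer1 knockout and between 0.679 and 0.852 in Drosha knockout with an estimated correlation. The highly abundant Mir6236 fell in Dicer1 knockout from 43529 ± 5780 to 24453 ± 1993 TPM (-0.83 ± 0.17), and leaving it out there called 3645 genes. In batch 2 it stood at 3986 ± 5662 TPM in the empty vector and 746 ± 180 TPM in Drosha knockout (-1.24 ± 0.98, limma adjusted p = 0.348). These values come from captured mRNA and do not measure a mature microRNA.

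The pooled seed test was chosen only after the families had been seen. If lost repression by many microRNAs adds up, genes with sites for more of the 25 test families should change more. The coefficient was ranked among those of random sets of 7-mers. Per family it was 0.012 in Drosha knockout, where 95% of random sets gave -0.00596 to 0.0014. In Dicer1 knockout it was 0.0167, where they gave -0.00658 to 0.00858. Both had a permutation p = 0.000999, the smallest possible value. With any one library left out the coefficients were 0.0111 to 0.0133 and 0.0124 to 0.0185. The single families had already been seen to lean this way, with 24 and 19 of 25 above the random median. Pooling them restates that and is no further support, so an effect spread over many families stays open. The random 7-mers were not matched for conservation.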
